A study of Mus musculus with 5 samples.

How the data were processed

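Hippocampi of C57BL/6 knock-in and wild-type mice were lysed, and RNA-protein complexes were precipitated with anti-HA (Covance) or mouse control IgG on Dynabeads Protein G, per the labels. Libraries were made with the NEBNext Ultra kit and sequenced on an Illumina HiSeq with 50 cycles, single-end. The authors' processing notes name TopHat and TopHat2 with the genome builds GRCm38 and mm10. The deposited region lists were written with rtracklayer 1.28.9, per the file headers. The program that called the regions is not given in the sources used here. Regions span whole bins with 1 bin size per chromosome in each list, as read from the values. On some chromosomes the size differed between lists, such as 240 and 200 bp on chromosome 12 over IgG in mice 1 and 2.

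For each region the deposited lists hold other values per library, namely the number of reads of the HA library and of the control library, not scaled for library size. They also hold the authors' log-odds score for each library, in an unstated log base, and the authors' p-value, adjusted p-value and empirical false discovery rate, each between 0 and 1. The way the p-values were adjusted is not stated. The lists were not filtered on p. Each list pairs 1 HA library with 1 control: knock-in HA 1 with knock-in IgG 1, HA 2 with IgG 2, and each HA library with the single wild-type HA library. Libraries were assigned to lists from the list names, which number the mice as the labels do. Reads outside called regions are not in the lists, so library totals are unknown and no depth per sample can be given; the reads inside regions are given with the results. Called regions covered 14350 and 7394 kb over IgG, at 6.94 and 8.66 HA and 1.79 and 4.31 IgG reads per kb. Over wild type they covered 22782 and 18974 kb, at 6.78 and 8.79 HA and 7.97 and 9.54 wild-type reads per kb.

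The assignment was checked in the files. Regions with identical coordinates carried identical HA reads in both lists of mouse 1 (3212 of 3212) and of mouse 2 (1587 of 1587), and equal wild-type reads in 189 of 193. Gene identifiers were found in GENCODE M21 for 99.3%, 99.0%, 98.9% and 99.1%, in list order. A chi-square test of the HA pair over 191 identical regions gave p = 4.55e-07, and without Malat1 it gave p = 0.129 over 190 regions. The same chi-square test gave p = 0.583 for the 96 regions in the IgG lists of both mice. Over these regions the HA libraries, with Malat1 left out, differed by no more than sampling noise. The IgG pair differed (chi-square p = 4.92e-15 over 58 regions). Regions with identical coordinates are a small part of the lists, so this does not cover the libraries as a whole. The HA and the IgG libraries were counted as 2 samples each. Across the 92 regions used for limma, the log2 difference of the HA pair and that of the IgG pair had a correlation of -0.04.

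A region counted for a gene when the deposited annotation placed it on the gene, not when the gene was only the nearest. Gene sets of both mice were compared by Fisher's exact test over 21951 protein-coding genes and by 10000 draws that kept gene length in 10 classes, or chromosome and length. The place of regions within shared genes and on exons was compared with 1000 random placements. The 20 gene lists were NMDA receptor complex, other glutamate receptors, GABAergic synapse, presynaptic release, FMRP target mRNAs, WAVE complex and actin, translation control, voltage-gated and pump channels, immediate early genes, long noncoding RNAs, markers of astrocytes, oligodendrocytes, microglia, endothelium and blood, choroid plexus, pyramidal and granule neurons and interneurons, ribosomal proteins, oxidative phosphorylation and the mitochondrial genome. They were tested by 2-sided Fisher's exact tests against genes with a region in at least 1 list, with Benjamini-Hochberg adjustment at 0.05.

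Named genes followed a rule: Cyfip1, Fmr1, Grin1, Grin2a, Grin2b, Dlg4, Camk2a, Arc, Map1b and App always; for each control, and for all 4 lists, the 12 genes with the best worse rank by the authors' log-odds score; and up to 4 members per gene list. The gene sets, their tests, the gene lists, the naming rule and part of the alternatives were chosen before the data were examined. Chosen afterwards were the read ratios, their scaling by the median ratio of regions with at least 20 reads, the limits of 4-fold and 0.25-fold, the list medians against 10000 draws of genes in 5 classes of read number, the 10000 random gene lists with chromosome and 3 classes of read number kept, the list medians with the class of chromosomes and 3 classes of read number kept, the use of limma and the further alternatives. Read ratios were HA over control reads summed over a gene's regions; a control of 0 was set to a floor of 3 counts per gene and list. Their 95% intervals are counting intervals. Folds were combined over mice as the mean and SD of log2 values. For limma, 0.5 was added to the counts of 92 identical regions with at least 20 reads and IgG counts were scaled by the list median.

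The 4-fold limit, the gene list test, the overlap of gene sets and limma were tested on simulated data, and the list medians, the placement of regions and the off-gene regions were not. With 40 genes changed 8-fold, the 4-fold limit recovered 78.5% of them over IgG and 87.8% over wild type with 0 false calls on average. The list test found a planted list in 100% of 100 simulations with 0.04 false lists each, 3 of 100 pairs of independent sets passed the matched overlap, and limma recovered 98.8% of 20 changed regions with 0.8 false calls. Simulated counts held counting error only, with a separate control per mouse, and simulated sets shared no library. The real lists share libraries and the IgG pair differed beyond counting error, so these rates of false calls may not hold for them. Alternatives covered stricter adjusted p-values and scores, more reads, nearest genes, reciprocal overlap, backgrounds, scaling, chromosomes 12 and 15 alone, and leaving out replicates. Raw reads were not used here. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.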

Results

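RNA that came down with CYFIP1, a partner of the fragile X protein FMRP and a subunit of the actin-regulating WAVE complex, was sequenced from mouse hippocampus. RNA immunoprecipitation with an antibody against the HA tag was done on 2 knock-in mice, with control IgG on the same 2 knock-in mice and with anti-HA on 1 wild-type mouse, so 5 libraries fall into 3 groups of 2, 2 and 1. The deposited lists give regions in which an HA library was called over a control, with the reads of both libraries in each region. HA over IgG held 4191 regions in mouse 1 and 1920 in mouse 2, and HA over wild-type HA held 5355 and 5362. The HA reads inside the regions came to 99575 and 64055 over IgG, with 25747 and 31872 IgG reads in the same regions. Over wild type they came to 154408 and 166760, with 181527 and 180957 wild-type reads. These totals cover called regions only, so the depth of each library is unknown. The median region held 5, 6, 5 and 5 HA reads, in that order of the lists. Folds below are ratios of HA to control reads over all regions on a gene, relative to the median region ratio of the list. That median was 2.89 and 0.947 over IgG and 1.41 and 1.75 over wild type, among regions with at least 20 reads. Intervals are 95% counting intervals for 1 library pair; PCR reads are not independent molecules, so intervals and floors cover counting error only. The labels number the knock-in mice without further detail, so spreads between the pair and p-values may hold technical variation only. Scaling by the pooled ratio of a list in place of its median would shift log2 folds by -0.42 and -1.09 over IgG and by 0.73 and 0.93 over wild type, so genes near 1-fold have no fixed side. Over wild type, 1 region on a ribosomal RNA sequence holds 43.6% and 43.7% of the wild-type reads behind the pooled ratios. All coordinates are on mm10.

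The comparison of anti-HA with IgG in the knock-in mice asked which RNAs the tagged protein brought down beyond nonspecific capture. Cyfip1 mRNA itself held 6101 HA and 67 IgG reads in mouse 1 and 6186 and 115 in mouse 2, which is 42.3-fold over the list median (log2 5.40 ± 0.60 SD, n = 2). Higher still were 3 genes named for NHS, the gene of Nance-Horan syndrome. Nhsl1 held 2230 HA and 5 IgG reads and then 1672 and 21, 114-fold (log2 6.83 ± 0.62 SD, n = 2), and Nhsl2 held 6278 and 27 and then 7002 and 78, 87.3-fold (log2 6.45 ± 0.17 SD, n = 2). Nhs held 676 HA and 2 IgG reads in mouse 1 (117-fold, interval 32.2 to 966) and 827 and 3 in mouse 2 (291-fold, interval 99.3 to 1415). C77080, the gene of a further NHS-like protein, was 19.7-fold (log2 4.30 ± 0.56 SD, n = 2).

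Sptan1 and Sptbn1, genes of spectrin chains of the membrane skeleton, were also higher, Sptan1 at 14.6-fold (log2 3.87 ± 0.20 SD, n = 2) and Sptbn1 at 9.15-fold (log2 3.19 ± 0.22 SD, n = 2). Mprip, whose protein binds myosin phosphatase, was 8.42-fold and Srcin1, an inhibitor of Src kinase, was 8.35-fold. Dcaf10 was 10.7-fold in mouse 1 from 62 HA and 2 IgG reads (interval 2.84 to 90.4) and 14.8-fold in mouse 2, where over wild type it was 8.36-fold in mouse 1 and 1.07-fold in mouse 2. In all, 19 of 392 genes with at least 20 reads in both mice reached 4-fold in both, against 1.23 expected if the mice were independent. The 19 lie at 11 places in the genome, because Rgag4 shares the reads of Nhsl2, Yars those of C77080, and small transcripts or overlapping gene models share those of genes such as Sptan1, Sptbn1, Mprip and Nhs. Among the 392 genes, 21 reached 4-fold in mouse 1 and 23 in mouse 2, while each list taken alone gave 35 and 28. The NHS-like genes, Sptan1, Sptbn1, Mprip, Srcin1 and Dcaf10 lie outside the naming rule and were chosen after their values were seen, as were the 4-fold and 20-read limits and the scaling.

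The reads behind these sums covered 6.72 and 4.83 kb of Nhsl1 in mice 1 and 2, at 332 and 346 HA reads per kb. On Cyfip1 they covered 62.0 kb in 1 region in mouse 1 and 8.20 kb in 26 regions in mouse 2, so the mean was 98.4 and 754 HA reads per kb although the sums were close. The Nhsl1 region with the most HA reads lay on chromosome 10 from 18523681 to 18527040 and touched 3 exons and coding sequence. It held 1273 HA and 2 IgG reads and then 1380 and 17. The regions of Nhs and Nhsl2 with the most HA reads over IgG lay on chromosome X and touched coding sequence and the 3' UTR. For 92 regions with identical coordinates in both mice, limma on log2 read counts found 77 higher in HA than in IgG and 0 lower at an adjusted p of 0.05, and 77 at that limit unadjusted. The Nhsl1 region with the most HA reads had a log2 difference of 6.92 (SE 0.48, limma adjusted p = 0.000456) and was higher in 2 of 2 mice. A region of Wasf1, which encodes the WAVE1 subunit of the complex that holds CYFIP1, passed with a log2 difference of 0.90 (SE 0.32, limma adjusted p = 0.0426), but with the pooled ratio as the scale its limma adjusted p was 0.682. A pair of Dlgap3 regions did not pass (limma adjusted p = 0.0748 and 0.0778). With the mouse as a replicate block, 75 regions were higher, 74 of them among the 77. These regions had already been called for an excess of HA reads, so the 77 are not an independent test of binding.

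**Figure D1:**
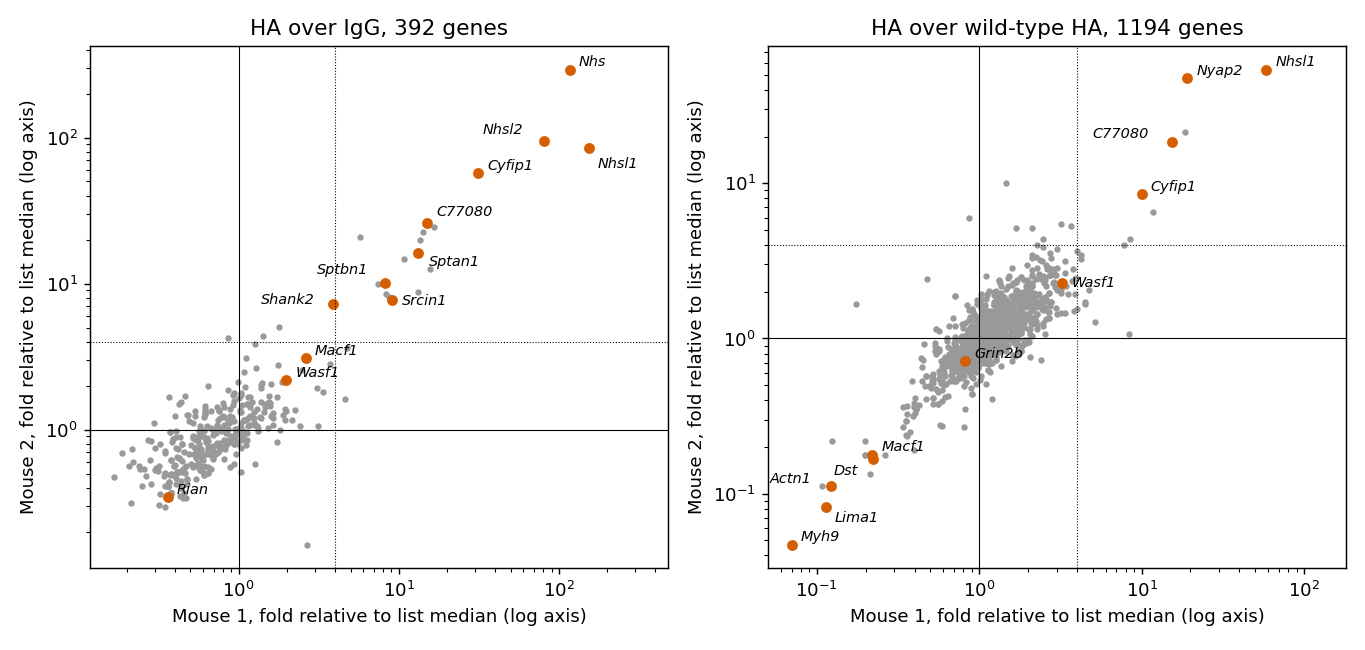
Fold of HA over control reads per gene in mouse 1 (x axis) against mouse 2 (y axis), both relative to the list median on log axes, over IgG (left, 392 genes) and over wild-type HA (right, 1194 genes). Each point is a gene with at least 20 reads in both mice, solid lines mark a fold of 1 and dotted lines a fold of 4, and Nhsl1, C77080 and Cyfip1 lie above the dotted lines in both panels.

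Both mice had an HA-over-IgG region on 799 genes, 668 of them protein-coding. Chance overlap of independent sets would give 90.1 protein-coding genes (odds ratio 38.2). Sets drawn with chromosome and gene length kept gave 447 on average and 480 at most in 10000 draws (permutation p = 0.0001, the smallest they can give). The draws took any protein-coding gene and kept neither expression nor read number. Genes with reads in any library of this tissue would also exceed them, so the p-value is no test of binding. The 12 genes that the naming rule took by the authors' log-odds score were Il31ra, Jarid2, Scaf11, Vps13b, Trappc9, Lmbrd2, Skp2, Samd12, Cntn1, Parvb, Mal2 and Nell2, 10 of them on chromosome 15. The range of the score differed by chromosome, in mouse 2 from 713 to 729 on chromosome 15 and from 3.14 to 36.2 on chromosome 12. Ranks by score therefore follow the chromosome in part. Of the 12, 6 had at least 20 reads in both mice, 6 lay above the list median in both and 0 reached 4-fold in both. Jarid2, a cofactor of the Polycomb complex, held 2286 HA and 558 IgG reads in mouse 1 (1.42-fold) and 2102 and 503 in mouse 2 (4.41-fold), in short regions. Its raw ratios were 4.10 and 4.18, so these folds differ through the list medians only. Neither region touched an exon. Cntn1, a neuronal adhesion molecule, was 0.864-fold and 1.88-fold. In mouse 2, HA reads did not exceed IgG reads in 782 of the 1920 listed regions, against 173 of 4191 in mouse 1. Per the authors' deposited values, 64.6% and 87.3% of the regions had an adjusted p below 0.05. Their empirical false discovery rate was below 10% for only 4.25% of the regions in mouse 1 and for 71.8% in mouse 2.

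The comparison with anti-HA from the wild-type mouse asked which RNAs needed the tagged protein to be brought down. Nhsl1 held 2230 HA and 27 wild-type reads in mouse 1 and 2549 and 27 in mouse 2, 56.2-fold over the list median (log2 5.81 ± 0.08 SD, n = 2). Both folds divide by the same wild-type library, so SDs over wild type hold no variation of the control. C77080 was 16.9-fold (log2 4.08 ± 0.19 SD, n = 2) and Cyfip1 was 9.23-fold (log2 3.21 ± 0.17 SD, n = 2), with 431 and 416 wild-type reads. Nyap2, whose protein binds phosphoinositide 3-kinase and the WAVE complex, held 27 HA reads and 1 wild-type read in mouse 1 (19.1-fold, interval 3.15 to 783) and 83 and 1 in mouse 2 (47.4-fold, interval 8.28 to 1896). Over IgG it held 13 HA and 3 IgG reads in mouse 1 (1.497-fold, interval 0.411 to 8.19) and had no region in mouse 2. Pim3, Slc11a2 and Hook1 also reached 4-fold in both mice, each from 2 or 3 wild-type reads and with lower interval bounds down to 1.62, 1.32 and 1.19. Over IgG, Pim3 was 1.04-fold and 1.74-fold and Slc11a2 0.638-fold and 0.880-fold, all with intervals that include 1, and Hook1 held 5 HA reads and 1 IgG read in mouse 1 and had no region in mouse 2. With Yars, which shares the reads of C77080, 8 of 1194 genes reached 4-fold in both mice. Simulated counting error alone, with the wild-type library shared, gave 0.24 on average and at most 3, but it holds no variation between mice or libraries, so the count does not show an effect of the tag. With at least 50 reads 4 genes passed, and with the pooled ratio as the scale 50 passed.

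Other mRNAs lay far lower in the knock-in HA libraries than in wild-type HA. Myh9, the heavy chain of nonmuscle myosin IIA, held 130 HA and 1307 wild-type reads in mouse 1 and 84 and 1020 in mouse 2, 0.0576-fold (log2 -4.12 ± 0.41 SD, n = 2). Over IgG Myh9 held 126 HA and 13 IgG reads in mouse 1 and 84 and 49 in mouse 2, above the list median in both. Lima1 was 0.0962-fold, Mical3 0.110-fold and Actn1, an actinin, 0.117-fold. Actn1 held 26 HA and 15 IgG reads and then 29 and 49, below the list median over IgG in both mice. Macf1, a linker of actin and microtubules, held 1353 HA and 4349 wild-type reads and then 1349 and 4329, 0.198-fold (log2 -2.34 ± 0.22 SD, n = 2), although it was 2.84-fold over IgG. Its raw ratios over wild type were 0.311 and 0.312, so this SD reflects the difference of the list medians. In all, 13 genes (14 identifiers, as Dst has 2) at 11 places lay at 0.25-fold or less in both mice, and a difference of the single wild-type mouse or library would also give this; the remaining places were Tuba1a, Dst, Pex5, Plec, Mapk8ip2 and a 5S ribosomal RNA gene. With the pooled ratio as the scale 5 genes at 4 places did so, namely Myh9, Lima1 with the overlapping Gm17058, Mical3 and Actn1, while Macf1 stayed below 1 with an upper bound of 0.389. Over IgG, 0 genes did so in both mice, with 8 and 1 per mouse. Of the genes in both paragraphs on wild type, all but Cyfip1 and Macf1 were chosen after their values were seen, as was the 0.25-fold limit. Sptan1, Sptbn1, Mprip and Srcin1 had no region in either wild-type list, so 13 of the 19 genes that were 4-fold over IgG could not be compared with wild type, while 6 had regions in both. Of other spectrin chains, Sptbn4 held 515 HA and 1730 wild-type reads in mouse 1 (0.211-fold, interval 0.191 to 0.233) and Sptb 12 and 28 (0.303-fold, interval 0.141 to 0.616), with no region over wild type in mouse 2.

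**Figure D2:**
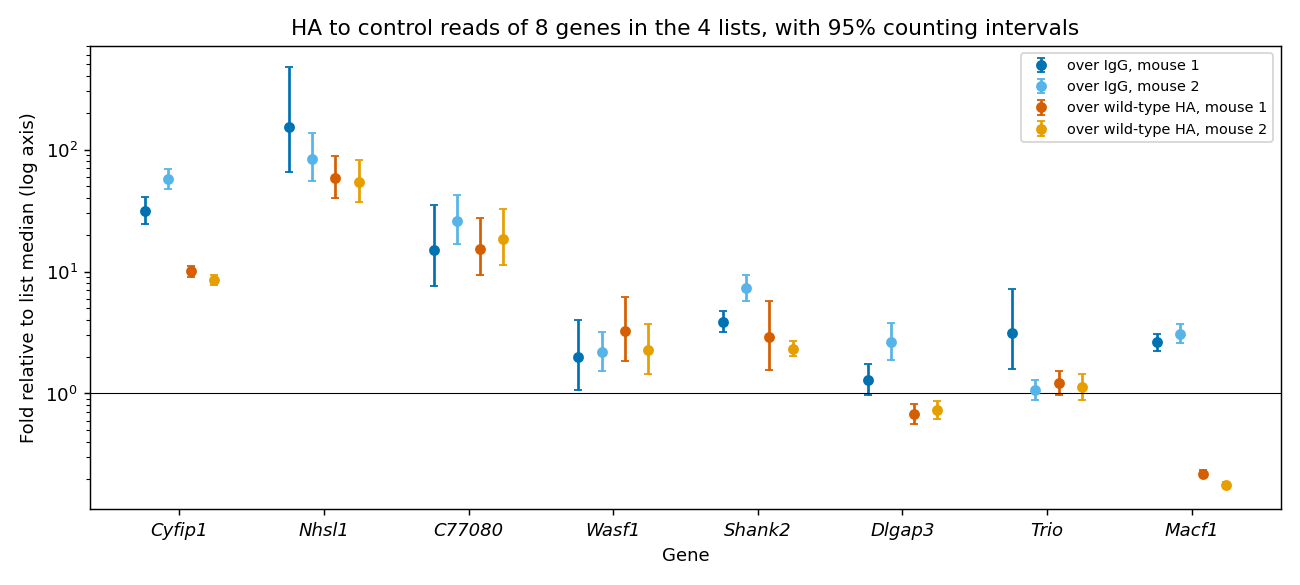
Fold of HA over control reads, relative to the list median on a log axis, for 8 genes (x axis) in each of the 4 lists. Points are single library pairs, bars are 95% counting intervals and the line marks a fold of 1; Cyfip1, Nhsl1, C77080, Wasf1 and Shank2 lie above 1 in all 4 lists, Macf1 lies below 1 over wild type, and so does Dlgap3, which the pooled scale turns to 1.13 and 1.38.

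Across genes, the log2 folds of both mice were correlated over IgG (Pearson r = 0.887, Spearman coefficient 0.771) and over wild type (Pearson r = 0.825, Spearman coefficient 0.761); genes are not independent replicates. Over wild type, both lists share 1 control library, and simulated data with only that library shared gave a Pearson r of 0.536 and a Spearman coefficient of 0.511. Both mice had a region over wild type on 2469 genes, 2046 of them protein-coding. Chromosome- and length-matched sets gave 1235 on average and 1292 at most (permutation p = 0.0001, the smallest they can give, odds ratio 73.9). Those draws treat the sets as independent, so they do not show how much overlap the shared control library adds. They also keep neither expression nor read number, so the p-value is no test of binding. The rule named Fgfr2, Macf1, Rybp, Rab43, Tia1, Tgfa, Prrt3, Tspan33, Ppp4r2, Zfp384, Zfp777 and Adcyap1r1, of which 10 lie on chromosome 6, 7 were above the list median in both mice and 2 below it in both. These ranks too follow the chromosome in part. In mouse 2 the score ran from 108 to 146 on chromosome 6 and reached at most 79.4 on chromosome 12. Tia1, an RNA-binding protein of stress granules, held 36 HA and 14 wild-type reads (1.82-fold) and 65 and 15 (2.48-fold). Fgfr2, a growth factor receptor, was 0.571-fold and 0.278-fold although it ranked high by score. Per the authors' deposited values, 82.3% and 78.8% of these regions had an adjusted p below 0.05. Their empirical false discovery rate was below 10% for 48.2% and 48.0%.

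The series title names the NMDA receptor complex, so its members were followed through all lists. Grin1, Grin2a, Dlg4 and Camk2a had no region in any list, nor did Map1b and App, which leaves their level unmeasured in these files. Grin2b, a receptor subunit, was 1.48-fold over IgG in mouse 1 (interval 0.755 to 3.16), had no region over IgG in mouse 2, and was 0.821-fold (0.708 to 0.953) and 0.712-fold (0.604 to 0.841) over wild type, which the pooled scale turns to 1.36-fold and 1.35-fold. Shank2, a scaffold of the postsynaptic density, was 3.89-fold and 7.29-fold over IgG and 2.89-fold and 2.32-fold over wild type, and stayed above 1 in all 4 lists under each scaling. Dlgap3, which links Shank proteins to the receptor, was 1.29-fold and 2.65-fold over IgG but 0.679-fold and 0.729-fold over wild type, or 0.966-fold in mouse 1 over IgG and 1.13-fold and 1.38-fold over wild type on the pooled scale. Over the measured members, the median was 1.30-fold (7 genes) and 2.97-fold (5 genes) over IgG and 0.692-fold (7 genes) and 0.712-fold (9 genes) over wild type, which the pooled scale turns in 3 of the 4 lists, to 0.970-fold in mouse 1 over IgG and 1.15-fold and 1.35-fold over wild type. The rank among random genes does not depend on the scale. Against random genes of similar read number, these medians had permutation p = 0.127, 0.019, 0.0634 and 0.0683 and adjusted p = 0.306, 0.156, 0.186 and 0.187 over 41 list medians. With random genes drawn from the same class of chromosomes as well (at least 500 regions in the list, or fewer), a test chosen after the data were seen, permutation p was 0.312, 0.991, 0.0315 and 0.0695 and adjusted p 0.640, 0.991, 0.180 and 0.285.

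FMRP target mRNAs had a median of 1.24-fold (19 genes) and 2.52-fold (14 genes) over IgG and 0.777-fold (20 genes) and 0.747-fold (22 genes) over wild type, which the pooled scale turns to 0.931-fold in mouse 1 over IgG and to 1.29-fold and 1.42-fold over wild type. Against random genes of similar read number the value of mouse 2 over IgG passed (permutation p = 0.0006, adjusted p = 0.0123), and the others had adjusted p = 0.174, 0.160 and 0.160. It did not pass with the class of chromosomes kept as well (permutation p = 0.542, adjusted p = 0.845): in that list 9 of the 14 members lie off chromosomes 12 and 15, where the 54 genes had a median of 4.23-fold, against 0.798-fold for the 665 genes on them. That list holds Sptan1, Sptbn1, Shank2 and Dlgap3 and was written from general knowledge, in part. Fmr1, the FMRP gene, had a single region, with 14 HA and 4 wild-type reads in mouse 2 (2.00-fold, interval 0.628 to 8.34). Arc, an activity-induced FMRP target, was 0.717-fold over IgG in mouse 2 and 0.582-fold and 0.517-fold over wild type. Members of the WAVE complex and actin list had a median of 1.99-fold over IgG in mouse 1 (5 genes) and 1.57-fold and 1.48-fold over wild type (8 and 9 genes), with adjusted p = 0.156, 0.203 and 0.160. Within it Wasf1 was 1.99-fold and 2.18-fold over IgG and 3.26-fold and 2.26-fold over wild type. Ribosomal protein mRNAs lay low over IgG, at 0.378-fold (3 genes) and 0.497-fold (5 genes), with adjusted p = 0.156 and 0.160, but were 1.06-fold (19 genes) and 0.921-fold (14 genes) over wild type, or 1.76-fold and 1.75-fold on the pooled scale, with adjusted p = 0.320 and 0.156. Transcripts of the mitochondrial genome were lower than random genes over IgG in mouse 1, at 0.273-fold (3 genes, permutation p = 0.0003, adjusted p = 0.0123), but did not pass with the class of chromosomes kept (permutation p = 0.0044, adjusted p = 0.0902). They had no region over IgG in mouse 2, so this could not be repeated there, and over wild type 1 of them was measured, mt-Rnr2, at 1.29-fold and 1.39-fold. Of 41 list medians these were the 2 that passed with read number kept, where 11 had an unadjusted p below 0.05; with the class of chromosomes kept 0 passed and 8 had an unadjusted p below 0.05.

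Genes with a region in all 4 lists numbered 749, 630 of them protein-coding. Chromosome- and length-matched draws gave 355 on average and 385 at most (permutation p = 0.0001, the smallest they can give, odds ratio 233). Both lists of a mouse use the same HA library, while the draws treat the sets as independent. Much of this overlap is therefore built in, and the p-value is no test of it. The rule took 12 genes, all on chromosome 15, among them Scube1, Trio, Ankrd33b, Nadk2, Skp2, Ep300, Dip2b, Slc4a8, Oplah, Fam135b and Sun2, with 2 to 215 HA reads in the IgG lists. As the range of the score differed by chromosome, this choice follows the chromosome in part. Over IgG 7 of the 12 lay above the list median in both mice and over wild type 10 did. Trio, a guanine nucleotide exchange factor, was 3.15-fold and 1.07-fold over IgG and 1.21-fold and 1.13-fold over wild type. Ankrd33b was 1.57-fold and 1.45-fold over IgG and 1.53-fold and 1.37-fold over wild type.

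Of the 20 gene lists, 0 had more or fewer members in all 4 lists than the 4727 genes with any region (2-sided Fisher's exact test, Benjamini-Hochberg), and 1 had an unadjusted p below 0.05. That list, long noncoding RNAs, held Meg3, Mirg and Rian, 3 of 5 measured members (Fisher's exact test, p = 0.0308, adjusted p = 0.586). Rian was 0.361-fold and 0.345-fold over IgG and 1.39-fold and 1.24-fold over wild type. Since 93.1% of the 749 genes lie on chromosomes 12 and 15, the lists were also set against 10000 random lists with chromosome and read number kept, a test chosen after the data were seen. By it 1 of 19 lists passed, WAVE complex and actin, with 3 members against 0.529 on average (permutation p = 0.0012, adjusted p = 0.0228). One of the 3 is Cyfip1, the gene of the tagged protein, and without it 2 of 10 members against 0.506 gave permutation p = 0.071. The NMDA receptor complex had 3 against 0.775 (permutation p = 0.0154, adjusted p = 0.146). Among synaptic lists, 3 of 14 NMDA receptor complex members (Dlgap3, Grin3a, Shank2), 2 of 12 other glutamate receptor genes (Cacng2, Pick1), 1 of 7 GABAergic synapse genes (Gphn) and 2 of 13 presynaptic release genes (Nrxn3, Rims2) were in all 4. FMRP targets had 6 of 29 (Adgrb1, Dlgap3, Dync1h1, Shank2, Trio, Ubr4) and the WAVE complex and actin list 3 of 11 (Cyfip1, Wasf1, Wasf2). Translation control had 2 of 12 (Eif2s1, Pum2), voltage-gated and pump channels 2 of 9 (Kcnq3, Scn8a) and immediate early genes 1 of 5 (Nr4a1). Ribosomal proteins had 4 of 32 (Rpl37, Rpl8, Rps29, Rps7), oxidative phosphorylation 3 of 25 (Atp5s, Ndufa6, Ndufb9) and the mitochondrial genome 0 of 3. Of the 4727 genes, 15.8% were in all 4 lists. Among cell markers, astrocytes had 1 of 4 (Slc1a3), oligodendrocytes 1 of 3 (Sox10), choroid plexus 1 of 1 (Prlr), microglia 0 of 1, endothelium and blood 0 of 1, pyramidal and granule neurons 0 of 6, and interneuron markers had no region in any list.

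Most regions touched an exon, although 35.8% to 39.9% of their bases were exonic. In the 4 lists, 86.9% (Wilson interval 85.8 to 87.9), 86.7%, 88.3% and 87.9% of regions touched an exon of the reference annotation. Coding sequence was touched by 73.3% to 75.6%. The 3' UTR was touched by 37.1% to 42.7%, the 5' UTR by 21.3% to 24.8%, and 9.11% to 10.8% lay in introns only. Among regions inside a gene, 86.8%, 86.3%, 87.9% and 88.5% touched an exon, against 44.6%, 47.4%, 48.0% and 46.3% when placed at random in the same genes (permutation p = 0.000999, the smallest they can give). Of mouse 1's regions, 22.1% overlapped one of mouse 2's over IgG (Wilson interval 20.9 to 23.4) and 52.3% over wild type (51.0 to 53.6). Within genes called in both mice, 54.2% of regions overlapped over IgG against 22.4% with random placement, and 54.5% over wild type against 22.6% (permutation p = 0.000999, the smallest they can give). Random placement took in introns, so exonic reads of any spliced RNA would give both differences. Neither of them bears on binding.

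Regions were concentrated on few chromosomes. Of the 799 genes called over IgG in both mice, 423 lie on chromosome 12 and 301 on chromosome 15, together 90.6%, and for the 749 genes in all lists the share was 93.1%. Chromosomes with at least 500 regions numbered 5, 2, 6 and 5 and held 90.2%, 85.7%, 99.3% and 94.5% of the regions, with 23.1%, 6.51%, 32.3% and 23.1% of the protein-coding genes. Chromosome 1 held 838 regions over IgG in mouse 1 and 0 in mouse 2, where over wild type it held 1164 and 1299. Sptan1 and Sptbn1 lie on chromosomes 2 and 11, which held 0 regions in both wild-type lists. A single region at Gm26917 on chromosome 17 also covers the ribosomal RNA sequence Rn18s-rs5. It took 29.5% of HA and 43.6% of wild-type reads in the wild-type list of mouse 1, and 29.3% and 43.7% in that of mouse 2.

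**Figure D3:**
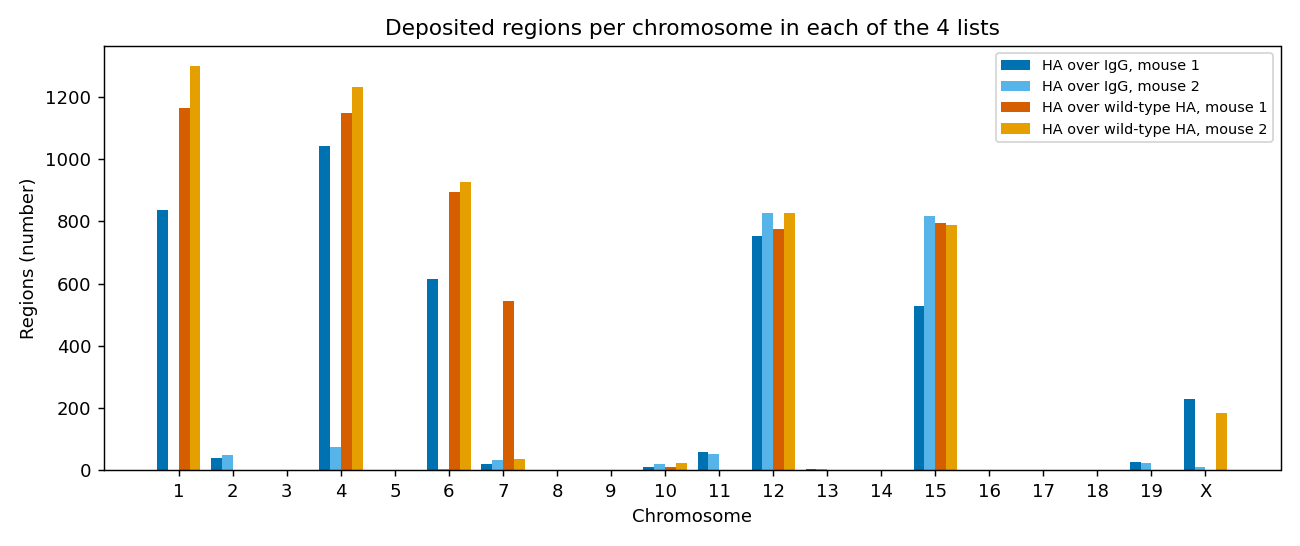
Number of deposited regions (y axis) on each chromosome (x axis) in the 4 lists, with bars starting at 0. Chromosomes 12 and 15 carry between 529 and 828 regions in every list, while chromosome 1 has 838 over IgG in mouse 1 and 0 in mouse 2.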

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

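All tests in this part were chosen after the results were seen. Regions that the deposited annotation places off any gene were not part of the comparisons by gene, and 3 of them reached 4-fold over at least 1 control in both mice. On chromosome 10 from 18318721 to 18319350, HA reads were 118 and 117 with 0 IgG reads in each mouse, at least 13.6-fold and 41.2-fold over the list median against a floor of 3 counts per region and list. Over wild type the same region held 118 and 117 HA reads with 2 wild-type reads each, 41.8-fold (interval 11.3 to 349) and 33.4-fold (9.05 to 279); GENCODE M21 places it on an exon of Nhsl1. On chromosome 14 from 104715801 to 104716000, 3197 HA and 357 wild-type reads in mouse 1 and 3141 and 354 in mouse 2 gave 6.34-fold and 5.07-fold (intervals 5.68 to 7.09 and 4.54 to 5.68), inside the noncoding gene D130009I18Rik in M21. On chromosome 6 from 123347601 to 123349800, 21 and 34 HA reads against 2 wild-type reads each gave 7.44-fold (1.82 to 65.4) and 9.71-fold (2.49 to 83.5), with no gene there in M21.

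Called regions crowded onto a few chromosomes. Region calling that differed between chromosomes and lists is a candidate explanation: in 6 of 13 cases a chromosome had at least 10-fold more regions in one list than in the other list of the same HA library, such as 1299 against 0 on chromosome 1 in mouse 2. RNAs bound by the tagged protein that come from those chromosomes would give similar chromosomes in both mice. Of mouse 1's regions over IgG, 65.0% lay on chromosomes with at least 10-fold fewer in mouse 2. Calling that differed between lists would also give this, as the chromosome 1 values of mouse 2 show. The value therefore cannot decide whether bound RNAs come from those chromosomes. Chromosomes 12 and 15 carried many regions in every list, so this value does not bear on them. The cause of their share of genes was not tested, and that share is not read as biology here.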

How the results depend on the processing

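Limma, the read ratios and their alternatives, the random lists and genes with chromosome kept, the limit to chromosomes 12 and 15 and the ratio above the list median were chosen after the data were seen. A replicate block had been planned as an alternative, though the use of limma had not. Of 68 alternatives for counts and shares, 31 stayed within the set range and 37 moved. Of 128 for single gene lists, 127 stayed on the same side of the adjusted threshold and 1 became stronger, while the odds ratio crossed 1 in 27, over 14 of 19 lists that did not pass. Genes called in both mice over IgG, 799, fell to 261 at an adjusted p of at most 0.01, 136 at a log-odds score of at least the median, 207 with at least 20 HA reads and 357 with ratios above the median. Over wild type, 2469 fell to 1294 and 1332 at those p and score limits, 646 with 20 HA reads and 856 on chromosomes 12 and 15. For all 4 lists, 749 fell to 110, 82, 181 and 275 at the limits of p, score, reads and ratio. Fewer regions enter each of these by construction. From single mice the counts were 1113 to 2703 over IgG, 3260 to 3721 over wild type and 1057 to 2297 for both controls. Overlap of regions over IgG, 22.1%, became 12.4% with reciprocal overlap of 50%, 14.8% at the stricter p, 50.6% of mouse 2's regions and 58.4% on chromosomes 12 and 15; over wild type 52.3% became 28.6%, 38.0% and 59.8%. Lists past the adjusted threshold numbered 0 to 1 from single mice; without replicate 2, ribosomal proteins passed (odds ratio 0.257, adjusted p = 0.0113). Against random lists with chromosome and reads kept 1 passed, WAVE complex and actin, with permutation p = 0.071 without Cyfip1. List medians that passed, 2, became 0 with the class of chromosomes kept. Exon shares at high scores were 82.7% and 87.9% over IgG and 86.8% and 85.5% over wild type, in mouse order. Genes at 4-fold over IgG, 19, numbered 28 to 35 from single mice. Over wild type, 8 became 4 with at least 50 reads, 5 at 8-fold, 50 scaled by the pooled ratio and 28 to 34 from single mice. In the totals behind that pooled ratio, 1 region holds 43.6% and 43.7% of wild-type reads in the lists of mice 1 and 2. Gene identifiers at 0.25-fold or less over wild type, 14, became 5 with the pooled ratio and 25 to 29 from single mice. Regions higher in limma, 77, numbered 75 with the replicate block, 66 with the pooled scale, 83 scaled by chromosomes 12 and 15 and 69 to 85 without single libraries. Except where construction shows it, the cause was not tested.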

Other observations

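All tests in this part were chosen after the results were seen. Members of further protein groups had regions without reaching 4-fold in both mice. Ppp1r9b, a scaffold of dendritic spines also called spinophilin, was 4.77-fold and 3.62-fold over IgG and had no region over wild type. Agap2 was 2.49-fold and 2.55-fold over IgG but 0.556-fold and 0.455-fold over wild type. Dync1h1, the dynein heavy chain, was 0.721-fold and 0.948-fold over IgG and 0.360-fold and 0.366-fold over wild type. Shank1 was 2.97-fold over IgG in mouse 2 and 0.954-fold and 0.868-fold over wild type. Malat1 was 1.36-fold and 1.41-fold over wild type and held 4115 and 5288 HA reads. Over regions with identical coordinates, the HA libraries differed with it and by no more than sampling noise without it. These genes were chosen after their values were seen.

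mRNAs of the NHS family held many more HA than control reads. Capture of Nhs, Nhsl1, Nhsl2 and C77080 by the beads or by any IgG would need a low fold over IgG. Their lowest in both mice was 15.03 (lower bound 7.54). These genes were picked for high folds in these lists, so this value is no independent test of that capture. Reads shared between similar sequences are argued against by 0% of 50-base words in common among family members and Cyfip1. For Nhsl1 and C77080, capture by the anti-HA antibody without the tagged protein would need a low fold over wild type, and the lowest was 15.4 (lower bound 9.35), but this rests on 1 wild-type library and so leaves that capture open. For Nhs and Nhsl2 it cannot be told apart from capture with the protein, since 1 of the 4 values needed over wild type had enough reads. That value, for Nhsl2 in mouse 1, came from 45 HA reads and 1 wild-type read (31.9-fold, interval 5.44 to 1286) and goes against such capture in 1 library pair, while mouse 2 held 5 and 0 reads. Capture of Nhsl1 and C77080 mRNA together with HA-tagged CYFIP1 stays open: their lowest fold over both controls in both mice was 15.03, but both genes were picked for high folds in these lists, so this value is no test of it. Of the 348 HA reads of C77080 in mouse 1, 335 lie in a region that also covers the last exon of Yars, and these 2 genes are not separated here. Nor are Nhsl2 and Rgag4. Over IgG, 6046 of the 6278 HA reads of Nhsl2 in mouse 1 and 6939 of 7002 in mouse 2 lie in 1 region that also covers Rgag4. NHS proteins carry a WAVE homology domain, as background; nothing here shows direct binding of the RNA.

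mRNAs of Macf1, Sptan1, Sptbn1, Mprip and Srcin1 also held more HA than IgG reads. For Macf1, capture in the anti-HA precipitate without the tagged protein may account for this: its higher fold over wild type was 0.220. The upper bound of 0.234 rests on the same 1 wild-type library, so capture with HA-tagged CYFIP1 stays open. For Sptan1, Sptbn1, Mprip and Srcin1, 0 of the 8 values needed over wild type exist, so capture without the tagged protein cannot be told apart from capture with it. With 1 wild-type library, a difference between that mouse or library and the knock-in pair also stays untested.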
